A study of Rattus norvegicus with 12 samples.

How the data were processed

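Expression was measured on 1-colour Affymetrix rat arrays with biotin-labelled cRNA made from total RNA, per the labels. The 12 arrays were placed in 6 groups by the treatment and tissue in their labels, and replicate numbers were taken from the same labels. Each array is a pool of tissue from 2 rats, so p-values measure the spread between pools and not between rats. The labels do not settle whether the 3 tissues came from the same rats, and they give the age at the start as 25 days in the sample labels and as 3 weeks in the series text. One label states daily dosing for 21 days and another collection 21 days after treatment, so the time from the last dose to collection is open, and the control is called saline in one place and solvent in another.

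The deposited values are intensity signals, 1 per probe set, on a linear scale in arbitrary units, made with GCOS 1.1 per the submitters' processing notes. The algorithm, the background correction and the scaling target are not given in the sources used here. From the values, the mean of each array after trimming 2% at each end lay between 500.124 and 500.151, so each array had been scaled as a whole. There were no missing values and no identical arrays. The medians of the arrays, saline replicates 1 and 2 and then acrylamide replicates 1 and 2, were 197, 197, 195 and 197 in the cerebellum, 199, 190.4, 191 and 192 in the spinal cord, and 179, 162, 182 and 172 in the sciatic nerve. The number of arrays limits the precision: the median standard error of a log2 difference was 0.16 in each tissue. The model shares 1 spread per probe set between the 6 groups, so this value does not compare the tissues.

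Of 31099 probe sets, 57 control probe sets were left out of the tests. The platform annotation gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780. Symbols were updated through the RefSeq gene table of assembly GRCr8, by gene ID for 20758 probe sets and by transcript accession for 2, and were kept for 66; 1 symbol changed, and 14217 different symbols resulted. No gene was named from a probe set with several symbols or none, with 1 exception given by its probe set ID. No genome coordinates were used. Probe sets whose names end in _a, _s or _x can bind several transcripts, and those of gene families such as glutathione transferases or Hspa1a and its copy can bind relatives.

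The tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where the text says otherwise. Values were analysed as log2(signal + 16), so a difference of a dim gene is understated. Probe sets were tested in a tissue where their mean over its 4 arrays lay above the 40th percentile of all means of probe sets by tissue (a signal of 110), which left 21347 in the fit. A single limma 3.58.1 model (lmFit, eBayes with an intensity trend) held 1 mean for each of the 6 groups, with 6 residual and 3.14 prior degrees of freedom, under R 4.3.3. Contrasts were acrylamide minus saline in each tissue, their average over the 3 tissues, an F test of their differences between tissues, and saline spinal cord against cerebellum and saline sciatic nerve against spinal cord, these last with at least a 2-fold difference. P-values were two-sided and adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05.

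The 59 gene lists held 1388 memberships, of which 1206 were on the arrays, and a list was tested where at least 5 members passed the filter. A gene with several probe sets was represented by the one with the highest mean. Camera compared each list with all other genes at a preset correlation of 0.01, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry, a self-contained test of whether the genes move on balance one way that makes no comparison with other genes, were alternatives. Tests of lists on the average and on tissue differences were added after the data were seen.

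Named genes were those with 1 symbol past the threshold and with both acrylamide arrays on the same side of both saline arrays, up to 12 in each direction, filled up with the smallest p to 10 in a tissue. For the average and the tissue differences they were the 6 with the smallest p, for tissue against tissue the 6 largest in each direction, and for a described list up to 4 members with the smallest p. Markers of other cell types were named where they moved with a group.

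Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a 60th percentile filter, eBayes without a trend or robust, 1 probe set per gene, a threshold of 0.1, the replicate number as a fixed block within tissues or over all tissues, a random block for treatment by replicate number (duplicateCorrelation with statmod 1.5.0, correlation 0.125), a fit of each tissue alone, acrylamide arrays in the tissue contrasts, and each array left out in turn. Added after the data were seen were fits without the 3 arrays with the most muscle or fat signal and without both replicate 1 arrays of the sciatic nerve.

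The procedure was tested on simulated data in 10 runs with 200 changed probe sets each. At changes of 1.5-fold, 2-fold and 4-fold, 23.0%, 63.7% and 93.3% were recovered in the cerebellum, 24.6%, 66.9% and 92.3% in the spinal cord, and 25.5%, 69.4% and 95.3% in the sciatic nerve, with 3.6%, 5.7% and 4.1% false calls. Each simulated probe set had 1 spread in all 3 tissues, so these shares do not cover tissues that vary unequally. On the real arrays the saline replicates correlated at 0.982 in the cerebellum, 0.9805 in the cord and 0.966 in the nerve. Lists of 20 genes shifted by 0.3 were called in 100% of cases in each tissue, and unshifted lists in 0% in the cerebellum, 1% in the spinal cord and 2% in the sciatic nerve. The simulated genes varied independently of each other, so these shares do not hold for lists whose genes move together on the real arrays. For those, exchanged treatment labels were used on the average over the 3 tissues alone. List calls in single tissues were not tested in that way. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.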

Results

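The arrays measured messenger RNA in the cerebellum, spinal cord and sciatic nerve of young male Wistar rats that received acrylamide or saline by mouth. Acrylamide is an electrophilic vinyl monomer that reacts with thiol groups, is conjugated to glutathione, and is known to damage long axons and nerve endings. Each of the 3 tissues had a saline and an acrylamide group with 2 arrays per group, which gave 12 arrays in 6 groups, and each array carried RNA pooled from 2 rats. The dose was 30 mg/kg per day for 21 days. The median signal of an array lay between 162 and 199 arbitrary units, and the number of arrays limits the precision. Signals are means ± SD over n = 2 arrays, and differences are log2 differences (acrylamide minus saline) ± the standard error from limma.

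The tissues were first compared in saline rats, to describe them and to set known markers beside their labels. Gene lists were not tested in these comparisons. Where arrays of the dimmer tissue lay under the filter's signal of 110, that signal stands in for them and the fold is a lower bound, a choice made after the data were seen. Pmp2 (probe set 1395333_at), a fatty acid-binding protein of peripheral myelin, had a signal of 4929 ± 401 (SD, n = 2) in the spinal cord and 9.9 ± 2.8 in the cerebellum. Prx, which encodes the myelin protein periaxin, had signals of 6619 ± 981 and 50.1 ± 4.9. Gabra6 (1378341_at), a GABA receptor subunit of granule neurons, had signals of 1.3 ± 0.5 in the cord and 13573 ± 102 in the cerebellum. Pcp2, a Purkinje cell gene, had signals of 64.1 ± 13.9 and 13295.5 ± 495. Pmp2 was at least 39.2-fold higher in the cord (limma's Benjamini-Hochberg adjusted p = 3.55e-08) and Prx at least 52.4-fold (3.56e-07), and Gabra6 was at least 108-fold (0.000258) and Pcp2 at least 106-fold (0.000761) higher in the cerebellum. Scn7a, Chodl, Mlip and Myoc (at least 47.7-, 32.7-, 42.8- and 28.1-fold) were also among the most increased genes in the cord by log2 difference, and Neurod1, Ttr, En2 and Fat2 (at least 117-, 111-, 28- and 39.5-fold) among the most decreased. In all, 4423 of 20483 probe sets passed an adjusted p of 0.05 and a 2-fold difference in limma, 2468 of them higher and 1955 lower in the cord.

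Against the spinal cord, the sciatic nerve of saline rats had Fabp4 (1368271_a_at), the fatty acid-binding protein of fat cells, among its most increased genes and Mog (1398257_at), a myelin protein of oligodendrocytes, among its most decreased. Fabp4 had a signal of 6069 ± 5957 (SD, n = 2) in the nerve, from 10281 and 1857 on replicates 1 and 2, and of 32.9 ± 17.8 in the cord. Mog had signals of 150 ± 192 and 6258 ± 78.1. Fabp4 was at least 34.9-fold higher in the nerve (limma adjusted p = 5.76e-05), and Mog at least 32.2-fold higher in the cord (0.00119). Dmbt1, the fat hormone gene Adipoq, Ces1d, the lipid droplet gene Cidec and Col9a1 followed on the side of the nerve, at least 12.4-, 16.6-, 18.3-, 5.79- and 12.5-fold. Mobp, the astrocyte water channel gene Aqp4, Fabp7, the serotonin receptor gene Htr2c and Edil3 followed on the side of the cord, at least 32.2-, 26.5-, 31.8-, 28.6- and 29.4-fold. For Mog and these 5, 1 of the 2 nerve arrays lay under 110. Of 20242 probe sets, 5278 passed the same test, 2144 higher and 3134 lower in the nerve.

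Markers of neighbouring tissues differed between replicates of the same group. Acta1, the actin of skeletal muscle, had a signal of 13974 on spinal cord saline replicate 1 and of 376, 209 and 212 (saline 2, acrylamide 1 and acrylamide 2) on the other cord arrays. In the sciatic nerve, Acta1 was at 1692 and 202 on the saline arrays and at 519 and 7532 on the acrylamide arrays, and Fabp4 at 10281 and 1857 on the saline arrays and at 2855 and 4222 on the acrylamide arrays. Pcp2 was at 1597 and 2294 on replicate 1 of the saline and acrylamide nerve groups, and at 162 and 148 on replicate 2. Over 17 genes restricted to the cerebellum, a set chosen after the data were seen, the nerve signal was 10.98% and 13.8% of the cerebellar one on the replicate 1 arrays and 1.62% and 1.33% on the replicate 2 arrays.

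**Figure D1:**
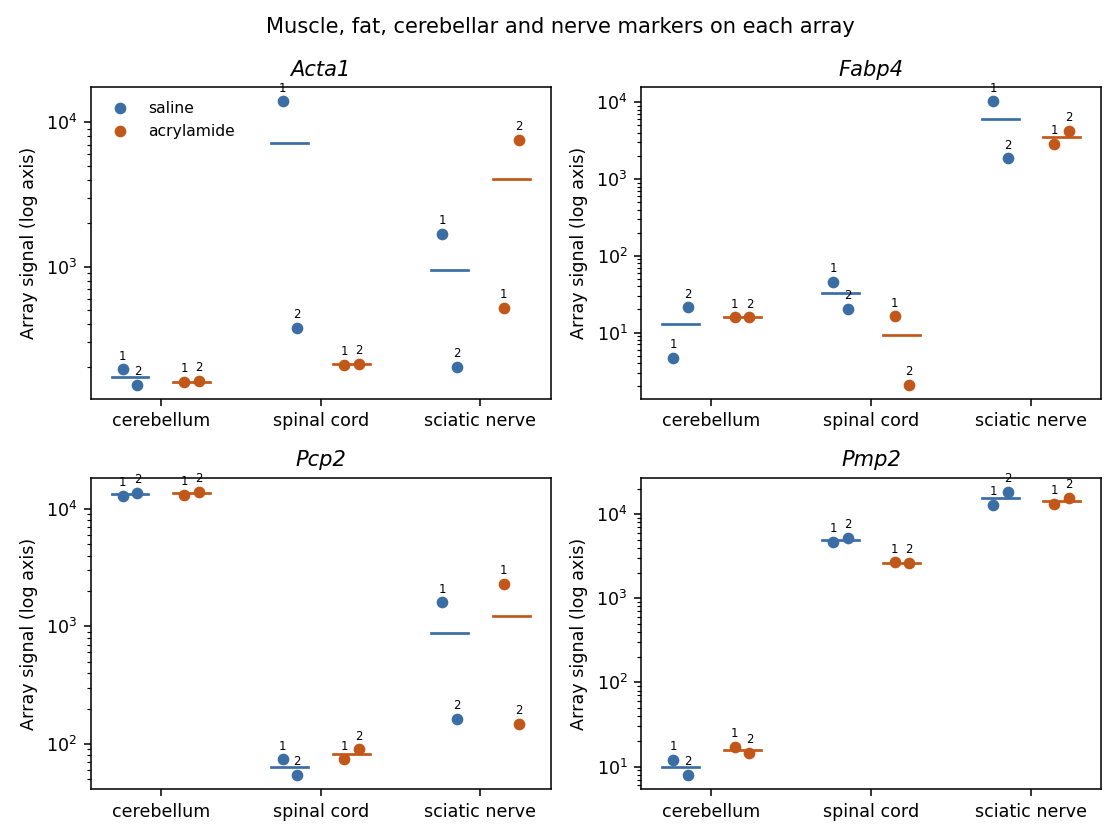
Signal of Acta1 (skeletal muscle), Fabp4 (fat cells), Pcp2 (Purkinje cells) and Pmp2 (peripheral myelin) in the deposited units on a log axis, with 1 point per array numbered by replicate and a horizontal line at each group's mean (n = 2). Acta1 reached 13974 on spinal cord saline replicate 1, and Pcp2 reached 1597 and 2294 on the replicate 1 arrays of the sciatic nerve.

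The cerebellum, which coordinates movement, was compared between acrylamide and saline rats. Immediate early genes, which neurons transcribe soon after activity, fell as a list, and genes of glutathione conjugation, the interferon response, antigen presentation by MHC class II and microglia rose as lists. These 5 calls ended, at an adjusted p = 0.145 to an adjusted p = 0.88 with an estimated correlation. The orphan nuclear receptor gene Nr4a3 (1369067_at) had a signal of 1017 ± 137 (SD, n = 2) in saline and 179 ± 43.5 in acrylamide arrays, and its relative Nr4a2 (1369007_at) had signals of 844 ± 69.1 and 283 ± 121. The glutathione transferase gene Gsta4 (1372297_at), whose enzyme clears lipid aldehydes, had signals of 379 ± 13.1 in saline and 625 ± 54.9 in acrylamide arrays. Gfap, the filament protein of astrocytes, had signals of 6773 ± 659 and 9652 ± 260. Both acrylamide arrays lay on the same side of both saline arrays for each of these 4 genes.

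Of 17 immediate early genes tested in the cerebellum, 12 were lower and 5 higher, with a mean log2 difference of -0.61 (camera adjusted p = 3.46e-05, and adjusted p = 0.566 with an estimated correlation). No member passed limma over all genes, 6 lower and 3 higher had an unadjusted p under 0.05, and adjusted over the list alone 5 lower and 2 higher passed. Those lower were Nr4a3 (-2.42 ± 0.32), Nr4a2 (-1.58 ± 0.24), Nr4a1 (-1.20 ± 0.25), Fos (-2.11 ± 0.49) and Klf2 (-0.86 ± 0.23). Those higher were Ier5 (0.41 ± 0.09) and Dusp6, a phosphatase that limits MAP kinase signals (0.39 ± 0.12). NRF2 and glutathione genes rose: 20 of 23 were higher, with a mean of 0.20 (camera adjusted p = 1.25e-05, and adjusted p = 0.145 with an estimated correlation). No NRF2 member passed over all genes in limma, 5 had an unadjusted p under 0.05, and 2 passed adjusted over the list alone, Gsta4 (0.69 ± 0.14) and Gstp1 (0.38 ± 0.10).

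Interferon-induced genes rose in the cerebellum, with 16 of 18 higher and a mean log2 difference of 0.38 (camera adjusted p = 5.12e-08, and adjusted p = 0.506 with an estimated correlation). None passed limma over all genes, 7 had an unadjusted p under 0.05, and 1 passed adjusted over the list alone. That gene was Gbp2 (1368332_at), a guanylate-binding protein, with signals of 84.8 ± 3.1 and 148 ± 9.4 (SD, n = 2) and a difference of 0.70 ± 0.12, beside Mx2 at 0.85 ± 0.31. All 7 MHC class II genes were higher, with a mean of 0.72 (camera adjusted p = 0.00018, and adjusted p = 0.778 with an estimated correlation). Among them was Cd74, whose product escorts MHC class II chains, with signals of 394 ± 106 and 813 ± 32.3. In limma 0 of the 7 passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Microglia and macrophage markers rose, with 18 of 19 higher and a mean of 0.42 (camera adjusted p = 1.25e-05, and adjusted p = 0.88 with an estimated correlation). Of these markers 3 had an unadjusted p under 0.05 in limma, 0 passed over all genes, and 2 passed adjusted over the list alone, Lgals3 (0.99 ± 0.26) and Gpnmb (0.81 ± 0.22). Reactive astrocyte genes rose, with 11 of 13 higher and a mean of 0.19 (camera adjusted p = 0.00166, and adjusted p = 0.506 with an estimated correlation). Among the astrocyte genes 3 had an unadjusted p under 0.05, 0 passed limma over all genes, and 2 passed adjusted over the list alone, S1pr3 (0.67 ± 0.15) and Gfap (0.51 ± 0.14). Without saline replicate 2, camera's adjusted p was 0.0964 for MHC class II genes (mean 0.50) and 0.134 for reactive astrocyte genes (mean 0.15), so both calls ended. Without saline replicate 1 the mean of the astrocyte genes was 0.32.

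Smaller shifts passed for 3 other lists in the cerebellum. Cholesterol synthesis genes fell, with 17 of 20 lower and a mean log2 difference of -0.10 (camera adjusted p = 0.00445, and adjusted p = 0.992 with an estimated correlation), led by Msmo1 at -0.23 ± 0.11. Myelin genes of Schwann cells, several of which oligodendrocytes also express, fell with a mean of -0.10 over 14 members (camera adjusted p = 0.0441, and adjusted p = 0.992 with an estimated correlation), led by Ugt8, an enzyme of myelin lipid synthesis, at -0.33 ± 0.10. Autophagy and lysosome genes rose with a mean of 0.06 over 26 members (camera adjusted p = 0.0284, and adjusted p = 0.506 with an estimated correlation). The lysosomal cholesterol carrier gene Npc2 (0.30 ± 0.06) was the member that passed limma adjusted over the list alone. No member of these lists passed limma over all genes, and 0, 1 and 3 had an unadjusted p under 0.05. The cholesterol call ended without saline replicate 2 (camera adjusted p = 0.16). The myelin call ended without saline replicate 2 (0.315) or acrylamide replicate 1 (0.32) and with a pseudocount of 64 (0.059), and the lysosome call ended without saline replicate 1 (0.16), saline replicate 2 (0.0859) or acrylamide replicate 2 (0.23).

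Gene by gene, limma with Benjamini-Hochberg adjustment called 0 of 18820 probe sets in the cerebellum, with 510 at an unadjusted p under 0.05 (241 higher and 269 lower), where chance alone gives 941. The spread used here is shared with the other tissues, and a fit of the cerebellum arrays alone had 975 of 18625 at that p. In the shared fit the smallest adjusted p was 0.494, for Nr4a3, Nr4a2 and Cav2, which encodes a caveolin and had a log2 difference of -0.62 ± 0.09. The other genes with the smallest p were C1qtnf12 (0.96 ± 0.18), the histone variant gene Macroh2a1 (0.41 ± 0.08) and the dynein light chain gene Dnal1 (-0.67 ± 0.14). Both acrylamide arrays lay above or below both saline arrays for 33.7% of probe sets, against 33.3% by chance. The count became 1 without saline replicate 2 and 2 without acrylamide replicate 1. There Nr4a2 had a difference of -2.01 and an adjusted p of 0.0174 (0.0174 to 0.9999 over 16 alternatives chosen beforehand). Lists of neurons and axons did not pass camera: 23 neurofilament and neuronal cytoskeleton genes had a mean of -0.006 and a median of -0.003 while the test leaned upward (adjusted p = 0.951). The 16 Purkinje cell markers had a mean of -0.001 (0.987), 19 kinesin and dynein transport genes -0.01 (0.684) and 25 synaptic vesicle genes 0.03 (0.908).

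In the spinal cord, which holds the cell bodies of motor neurons and the long tracts, genes of Schwann cell myelin, collagen and cholesterol synthesis fell as lists with acrylamide, and NRF2, interferon-induced, clock and lysosome genes rose as lists. None of these 7 stayed, at an adjusted p = 0.183 to an adjusted p = 0.816 with an estimated correlation. Pmp2, the peripheral myelin gene, had a signal of 4929 ± 401 (SD, n = 2) in saline and 2659 ± 21.1 in acrylamide arrays, a log2 difference of -0.88 ± 0.16. Col1a1, a chain of type I collagen, had signals of 4450 ± 48.7 and 2805 ± 512. Entpd5 (1372774_at), a nucleotidase that serves protein glycosylation in the endoplasmic reticulum, had the smallest p, with signals of 934 ± 33.4 and 1485 ± 77.7 and a difference of 0.66 ± 0.09 (limma adjusted p = 0.669). Both acrylamide arrays lay on the same side of both saline arrays for these 3 genes.

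NRF2 and glutathione genes rose in the spinal cord, with 18 of 24 higher and a mean log2 difference of 0.18 (camera adjusted p = 6.66e-06, and adjusted p = 0.183 with an estimated correlation). No member passed limma over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05. They were led by Me1 (0.26 ± 0.07), which supplies NADPH, Gstp1 (0.35 ± 0.10), Gsta1 (0.53 ± 0.18) and Gstm1 (0.32 ± 0.12). Interferon-induced genes rose, with 21 of 24 higher and a mean of 0.23 (camera adjusted p = 4.32e-05, and adjusted p = 0.74 with an estimated correlation). In limma 3 of them had an unadjusted p under 0.05 and 0 passed either adjustment, with Mx2 at 0.75 ± 0.31 and Gbp2 at 0.36 ± 0.12. Autophagy and lysosome genes rose, with 23 of 26 higher and a mean of 0.09 (camera adjusted p = 0.000669, and adjusted p = 0.384 with an estimated correlation). Of 3 members at an unadjusted p under 0.05, Npc2 (0.27 ± 0.06) passed limma adjusted over the list alone. Circadian clock genes rose, with 11 of 15 higher and a mean of 0.12 (camera adjusted p = 0.00186, and adjusted p = 0.568 with an estimated correlation). The clock repressor gene Nr1d1 (0.63 ± 0.14) and the clock output gene Dbp (0.35 ± 0.10) passed adjusted over the list alone. Microglia and macrophage markers rose, with 20 of 23 higher and a mean of 0.27 (camera adjusted p = 0.000808, and adjusted p = 0.909 with an estimated correlation). In limma 1 of these markers had an unadjusted p under 0.05 and 0 passed either adjustment. The clock call ended without saline replicate 1 (camera adjusted p = 0.0583) or acrylamide replicate 2 (0.0806), and the microglia call without acrylamide replicate 1 (0.0534).

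Collagen and extracellular matrix genes fell in the spinal cord, with 31 of 36 lower and a mean log2 difference of -0.29 (camera adjusted p = 1.75e-14, and adjusted p = 0.61 with an estimated correlation). No member passed limma over all genes or adjusted over the list alone, and 12 lower members had an unadjusted p under 0.05. Among these were Col1a2 (-0.69 ± 0.22) and the laminin genes Lama2 (-0.46 ± 0.11) and Lamc1 (-0.36 ± 0.10). Myelin genes of Schwann cells fell, with 15 of 20 lower and a mean of -0.24 (camera adjusted p = 3.81e-05, and adjusted p = 0.816 with an estimated correlation). Of 4 myelin genes at an unadjusted p under 0.05, Pmp2 passed limma adjusted over the list alone. All 10 Schwann cell markers were lower, with a mean of -0.28 (camera adjusted p = 0.000525, and adjusted p = 0.74 with an estimated correlation). In limma 3 of the 10 had an unadjusted p under 0.05 and 0 passed either adjustment, with Prx at -0.62 ± 0.20 and the sodium channel gene Scn7a at -0.62 ± 0.22. Pmp22, a structural protein of peripheral myelin, was at -0.42 ± 0.08 on 1 probe set (1370504_a_at) and at -0.12 ± 0.095 on the brighter one used in the lists (1370247_a_at). Over 76 other genes abundant in the nerve, the median difference in the cord was -0.38 ± 0.05, with 71 of them lower. This standard error is taken over genes and does not measure the spread between arrays. The median was -0.18 for acrylamide replicate 1 and -0.58 for replicate 2. The mean of the collagen list was -0.45 without acrylamide replicate 1 and -0.13 without replicate 2. That of the Schwann cell markers was -0.18 without acrylamide replicate 2, and that of the myelin genes -0.14 without saline replicate 2. Camera's call stayed in each of these cases.

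All 20 cholesterol synthesis genes were lower in the spinal cord, with a mean log2 difference of -0.17 (camera adjusted p = 1.65e-06, and adjusted p = 0.816 with an estimated correlation). In limma 0 of the 20 passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05, Idi1 (-0.32 ± 0.12) and Mvk (-0.38 ± 0.15). Immediate early genes fell, with 13 of 17 lower and a mean of -0.22 (camera adjusted p = 0.0179, and adjusted p = 0.816 with an estimated correlation). Their lowest p were those of Egr2 (-0.79 ± 0.27) and Klf2 (-0.66 ± 0.23), which did not pass limma adjusted over the list alone. The immediate early call ended without saline replicate 1 (mean -0.15, camera adjusted p = 0.362) or acrylamide replicate 2 (-0.18, 0.162). Heat shock proteins fell, with 9 of 13 lower and a mean of -0.08 (camera adjusted p = 0.0491, and adjusted p = 0.575 with an estimated correlation). The stress-induced chaperone gene Hspa1a (-0.57 ± 0.13) and the small heat shock protein gene Cryab (-0.43 ± 0.11) passed limma adjusted over the list alone. That call ended without any 1 of the 4 cord arrays, with camera's adjusted p at 0.226 and 0.054 without saline replicates 1 and 2 and at 0.193 and 0.0662 without acrylamide replicates 1 and 2, and with a pseudocount of 64 (0.056). Cell cycle genes fell, with 19 of 24 lower and a mean of -0.19 (camera adjusted p = 0.0238, and adjusted p = 0.816 with an estimated correlation). The mean was -0.04 without saline replicate 2 (0.91), 0.006 without acrylamide replicate 2 (0.961) and -0.33 without acrylamide replicate 1, and the call ended under quantile normalization (-0.13, 0.204). Granulocyte and mast cell markers were also lower in the cord, with a mean of -1.845 over 6 genes (camera adjusted p = 0.00583, and adjusted p = 0.816 with an estimated correlation). Their call ended without saline replicate 2 (mean -1.42, 0.213) or acrylamide replicate 2 (-0.295, 0.708), and the mean was -3.38 without acrylamide replicate 1. The granulocyte gene S100a9 had a signal of 366.8 on acrylamide replicate 2 and of 3261, 5950 and 3951 on the others. In limma 0 members of the immediate early, heat shock and cell cycle lists passed over all genes, and 2, 2 and 1 had an unadjusted p under 0.05. Adjusted over the list alone 0 immediate early and 0 cell cycle genes passed.

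Skeletal muscle markers were lower in the acrylamide cord arrays, with a mean log2 difference of -2.55 over 15 genes (camera adjusted p = 7.46e-09, and adjusted p = 0.74 with an estimated correlation). The median signal of the list was 3642 on saline replicate 1 and 113, 67.0 and 63.0 on saline 2, acrylamide 1 and acrylamide 2. In limma 4 of them had an unadjusted p under 0.05 and 0 passed either adjustment. Without saline replicate 1 their mean was -0.05 and the call ended (camera adjusted p = 0.876), and without saline replicate 2 it was -4.72. Limma with Benjamini-Hochberg adjustment called 0 of 18967 probe sets in the spinal cord, with 544 at an unadjusted p under 0.05 (194 higher and 350 lower), where chance gives 948. A fit of the cord arrays alone, whose spread is not shared with the other tissues, had 1023 of 18625 at that p. The groups were apart for 33.6% of probe sets against 33.3% by chance. Other genes with the smallest p were Asph (0.48 ± 0.09), Tmem176b (0.50 ± 0.09), the retrograde transport receptor gene Kdelr3 (-0.75 ± 0.14), Dmpk (-0.48 ± 0.10), Abcd4 (-0.58 ± 0.12) and Dhrs4 (0.77 ± 0.16). Without acrylamide replicate 2 the count was 1. Neurofilament and neuronal cytoskeleton genes (25 tested, mean 0.03, camera adjusted p = 0.623), motor neuron markers (10 tested, mean -0.01, 0.837), synaptic vesicle genes (25 tested, mean -0.05, 0.676) and axon injury and regeneration genes (16 tested, 0.837) did not pass. For the last list the mean was 0.0 and the median 0.02 while the test leaned downward.

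The sciatic nerve, a mixed nerve of motor and sensory axons, was the tissue with a single gene past the test over all genes. Nr1d1 (1370816_at), which encodes the clock repressor REV-ERB alpha, rose from a signal of 167 ± 25.0 (SD, n = 2) in saline to 611 ± 16 in acrylamide arrays, a log2 difference of 1.78 ± 0.14 (limma adjusted p = 0.00866), with both acrylamide arrays above both saline arrays. Circadian clock genes rose as a list, as did repair Schwann cell genes, and genes of cholesterol and fatty acid synthesis fell as lists. Of these 4 calls 0 stayed, at an adjusted p = 0.154 to an adjusted p = 0.353 with an estimated correlation. Ngfr, the low-affinity neurotrophin receptor of repair Schwann cells, had signals of 180 ± 40.7 and 371 ± 26.1, and Insig1, which holds the sterol sensor in the endoplasmic reticulum, had signals of 5548 ± 960 and 3777 ± 112.5. Ddit4 (1368025_at), a stress-induced inhibitor of mTOR signalling, had signals of 2826 ± 104 and 1353 ± 243.5 and an adjusted p of 0.0634.

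Of 15 clock genes tested in the nerve, 9 were higher and 6 lower, with a mean log2 difference of 0.24 and a median of 0.05 (camera adjusted p = 0.000242, and adjusted p = 0.256 with an estimated correlation). Nr1d1 passed limma over all genes, and adjusted over the list alone 5 passed higher and 1 lower. Those higher were Nr1d1, Dbp (0.60 ± 0.10), Nr1d2 (0.71 ± 0.15), Per3 (0.53 ± 0.12) and Bhlhe40 (0.54 ± 0.15), and the lower one was the repressor gene Cry1 (-0.40 ± 0.11). The call of Nr1d1 ended without acrylamide replicate 1 (log2 difference 1.81) or replicate 2 (1.76). It also ended with the replicate number as a fixed block within tissues (limma adjusted p = 0.127). Over 16 alternatives chosen beforehand Nr1d1 was between 1.55 and 1.92 with an adjusted p between 0.00468 and 0.9998, and passed in 12. The highest came from a fit of the sciatic nerve arrays alone. Limma called 1 of 18088 probe sets in the nerve, Nr1d1, with 922 at an unadjusted p under 0.05 (493 higher and 429 lower), where chance gives 904. A fit of the nerve arrays alone, whose spread is not shared with the other tissues, had 320 of 18625 at that p. In the nerve the groups were apart for 26.3% of probe sets against 33.3% by chance. The count was 35 without saline replicate 1, 15 without saline replicate 2, 1 without acrylamide replicate 1, where the called gene was Ddit4 and not Nr1d1, and 0 without acrylamide replicate 2.

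**Figure D2:**
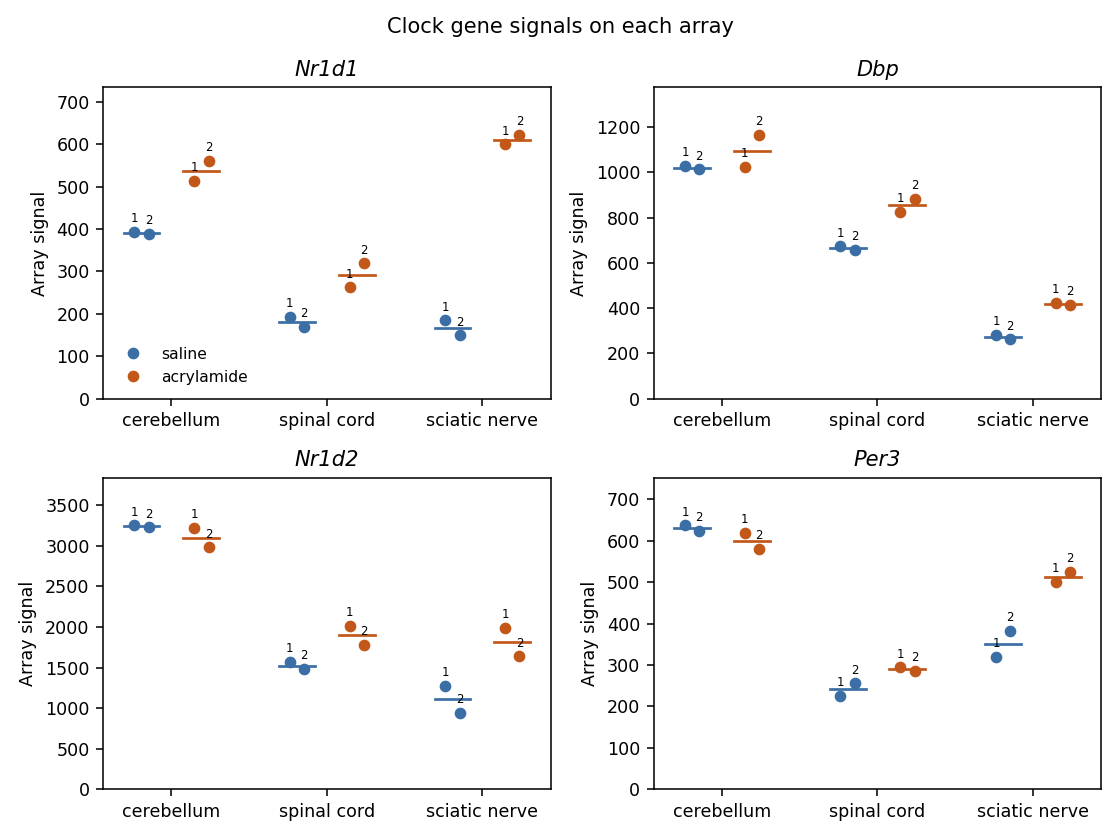
Signal of the clock genes Nr1d1, Dbp, Nr1d2 and Per3 in the deposited units on a linear axis from 0, with 1 point per array numbered by replicate and a horizontal line at each group's mean (n = 2). Nr1d1 in the sciatic nerve averaged 167 in saline and 611 in acrylamide arrays.

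Repair Schwann cell genes rose in the nerve, with 9 of 13 higher and a mean log2 difference of 0.33 (camera adjusted p = 0.000242, and adjusted p = 0.154 with an estimated correlation). None passed limma over all genes, 5 had an unadjusted p under 0.05, and the same number passed adjusted over the list alone: Ngfr (0.99 ± 0.18), Gfap (0.64 ± 0.14), the matrix gene Tnc (0.96 ± 0.27), the chemokine gene Ccl2 (0.83 ± 0.24) and Sox2 (0.48 ± 0.16). The mean was 0.20 without saline replicate 2 and 0.21 without acrylamide replicate 1. Without both replicate 1 arrays, which held cerebellar transcripts, it was 0.27 and the call ended (camera adjusted p = 0.242, the highest over the list's alternatives, of which the lowest was 3.9e-05). Reactive astrocyte genes, of which Gfap and Tnc are also repair genes, rose with 12 of 17 higher and a mean of 0.26 (camera adjusted p = 0.000504, and adjusted p = 0.353 with an estimated correlation). In limma 5 of the 17 had an unadjusted p under 0.05 and Gfap passed adjusted over the list alone. Their call ended without saline replicate 2 (mean 0.04, 0.297) or acrylamide replicate 2 (0.15, 0.0737), and the mean was 0.47 without saline replicate 1. Immediate early genes rose, with 15 of 18 higher and a mean of 0.33 (camera adjusted p = 0.000141, and adjusted p = 0.35 with an estimated correlation). In limma 5 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone, Dusp6 (0.51 ± 0.12), beside Egr1 (1.27 ± 0.39). The immediate early call ended without saline replicate 2 (mean 0.11, 0.103) or acrylamide replicate 2 (0.19, 0.0604), and the mean was 0.54 without saline replicate 1.

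All 20 cholesterol synthesis genes were lower in the nerve, with a mean log2 difference of -0.33 (camera adjusted p = 6.14e-14, and adjusted p = 0.353 with an estimated correlation). None passed limma over all genes, and 12 had an unadjusted p under 0.05. Adjusted over the list alone 1 passed, Insig1 (-0.54 ± 0.11), while Idi1 (-0.40 ± 0.12), Dhcr7 (-0.39 ± 0.12) and Mvk (-0.47 ± 0.15) did not (adjusted p = 0.0543 for each). Fatty acid synthesis genes fell, with 13 of 18 lower and a mean of -0.22 (camera adjusted p = 0.000606, and adjusted p = 0.154 with an estimated correlation). In limma 6 had an unadjusted p under 0.05 and 4 passed adjusted over the list alone: Fasn (-0.37 ± 0.09), Acaca (-0.32 ± 0.09), Acsl1 (-0.59 ± 0.18) and Dgat2 (-0.55 ± 0.17). Another probe set of Fasn (1367707_at) was at -0.41 ± 0.08. Fat cell markers moved with these lists: their mean was -0.45 over 15 genes (camera adjusted p = 0.00548, and adjusted p = 0.782 with an estimated correlation). Their median signal was 2563 and 474 on the saline arrays and 602 and 768.5 on the acrylamide arrays, and in limma 2 had an unadjusted p under 0.05 and 0 passed either adjustment. Without saline replicate 1 the means were -0.56 for cholesterol genes, -0.08 for fatty acid genes and 0.47 for fat cell markers. Without saline replicate 2 they were -0.11, -0.35 and -1.36. Without acrylamide replicate 1 the calls of the fatty acid genes (mean -0.13, camera adjusted p = 0.139) and fat cell markers (-0.25, 0.265) ended.

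NRF2 and glutathione genes rose in the nerve, with 18 of 26 higher and a mean log2 difference of 0.13 (camera adjusted p = 0.00735, and adjusted p = 0.292 with an estimated correlation). In limma 4 had an unadjusted p under 0.05, and Gstp1 (0.49 ± 0.10), with signals of 6901 ± 991 and 9681 ± 719 (SD, n = 2), passed adjusted over the list alone. That call ended without saline replicate 2 (mean 0.09, camera adjusted p = 0.0851) or acrylamide replicate 2 (0.07, 0.273). All 14 cell cycle genes were higher, with a mean of 0.25 (camera adjusted p = 0.000479, and adjusted p = 0.35 with an estimated correlation). In limma 1 of the 14 had an unadjusted p under 0.05 and 0 passed either adjustment, led by Cdc20 (0.45 ± 0.19). Myelin genes of Schwann cells fell, with 18 of 20 lower and a mean of -0.16 (camera adjusted p = 0.00121, and adjusted p = 0.782 with an estimated correlation), led by the nodal adhesion gene Nfasc (-0.43 ± 0.14). Their mean was -0.40 without saline replicate 1, turned to 0.07 without saline replicate 2 (0.482), and the call ended without acrylamide replicate 1 (0.0521). Myelin genes of oligodendrocytes fell with a mean of -0.19 over 17 genes (camera adjusted p = 0.0182, and adjusted p = 0.534 with an estimated correlation). Their mean was -0.30 without saline replicate 2 (0.419), 0.10 without acrylamide replicate 2 (0.704) and -0.38 without acrylamide replicate 1, and the call ended under quantile normalization (-0.15, 0.107). Of the Schwann cell and oligodendrocyte myelin genes, 2 and 1 had an unadjusted p under 0.05 in limma and 0 passed either adjustment. Beside them, markers of cerebellar granule neurons had a median signal of 321 and 445 on the replicate 1 arrays and 83.6 and 87.5 on the replicate 2 arrays.

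Skeletal muscle and fibroblast markers also rose in the nerve. All 18 muscle markers were higher, with a mean log2 difference of 1.246 (camera adjusted p = 0.000664, and adjusted p = 0.782 with an estimated correlation). Their median signal was 583 and 92.2 on the saline and 226 and 1811 on the acrylamide arrays. The muscle mean was 2.32 without saline replicate 1, 0.14 without saline replicate 2 (0.564), 2.46 without acrylamide replicate 1 and 0.05 without acrylamide replicate 2 (0.74). Nerve fibroblast and perineurial markers had a mean of 0.19 over 19 genes (camera adjusted p = 0.0143, and adjusted p = 0.782 with an estimated correlation). The glucose transporter gene Slc2a1 (0.39 ± 0.09) passed limma adjusted over the list alone. The fibroblast mean was 0.61 without saline replicate 1, -0.22 without saline replicate 2 (0.368), 0.40 without acrylamide replicate 1 and 0.07 without acrylamide replicate 2 (0.751). Endoplasmic reticulum (ER) chaperones rose with a mean of 0.07 over 18 genes (camera adjusted p = 0.0394, and adjusted p = 0.35 with an estimated correlation), led by Sdf2l1 (0.40 ± 0.11). Ribosomal protein genes had a mean of -0.04 over 23 genes (camera adjusted p = 0.0491, and adjusted p = 0.782 with an estimated correlation). Their direction turned under quantile normalization (mean 0.01, 0.483), and the call ended with a pseudocount of 64 (0.0507). For the chaperones, camera's adjusted p was 0.234 without saline replicate 1, 0.0803 without saline replicate 2 and 0.801 without acrylamide replicate 2 (mean -0.001). The mean was 0.15 without acrylamide replicate 1. For the ribosomal genes the adjusted p was 0.31 without saline replicate 1, 0.103 without saline replicate 2 and 0.954 without acrylamide replicate 1 (mean -0.01), and the ribosomal mean was -0.08 without acrylamide replicate 2. In limma 0 members of these lists passed over all genes, and 0 muscle, 1 fibroblast, 2 chaperone and 0 ribosomal genes had an unadjusted p under 0.05. Adjusted over the list alone Slc2a1 was the single gene that passed.

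Other genes with the smallest p in the nerve were Rgs16, a regulator of G protein signals (1.245 ± 0.18, limma adjusted p = 0.343), the neuropeptide gene Vip (-1.67 ± 0.28, 0.569), Mllt11 (-0.64 ± 0.12), Nr1d2 on another probe set (1370541_at, 0.81 ± 0.15) and Tmod3 (0.59 ± 0.11), the last 3 at an adjusted p of 0.701. Genes of the axon did not pass as lists: 24 neurofilament and neuronal cytoskeleton genes had a mean log2 difference of -0.03 (camera adjusted p = 0.707). Kinesin and dynein transport genes (18 tested) had -0.05 (0.459) and 15 axon injury and regeneration genes 0.01 with a median of 0.11 (0.126). In the injury list, 3 genes passed limma adjusted over the list alone, 2 higher and 1 lower, and none passed over all genes. The 18 synaptic vesicle genes had a mean of 0.04 and a median of -0.03 (0.5), with 3 at an unadjusted p under 0.05 in limma and 0 past it.

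**Figure D3:**
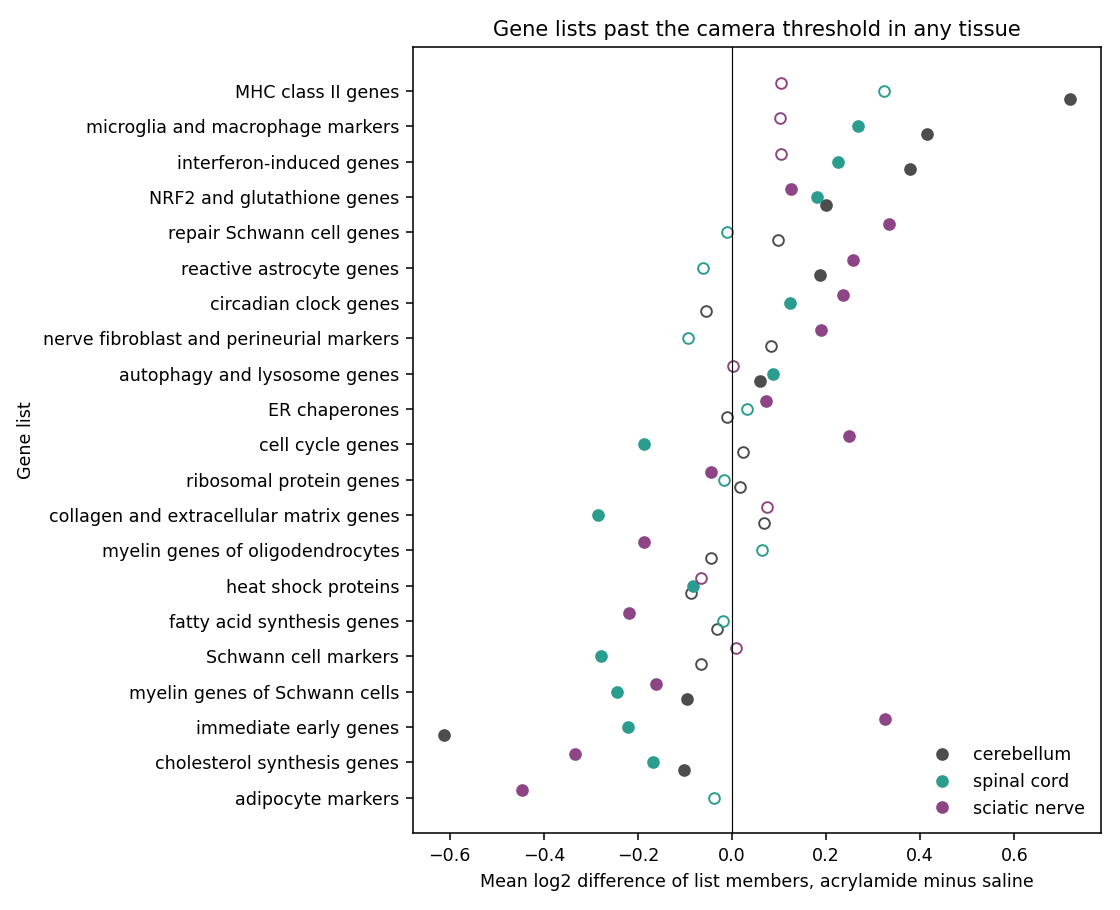
Mean log2 difference, acrylamide minus saline, over the members of 21 of the 23 gene lists that passed camera in any tissue, with 1 point per tissue, filled where the list passed an adjusted p of 0.05 with the preset correlation and hollow where it did not (skeletal muscle and granulocyte lists are left out for scale). Immediate early genes lay at -0.61 in the cerebellum and 0.33 in the sciatic nerve, cholesterol synthesis genes lay below 0 in all 3 tissues, and without saline replicate 2 the nerve points of the Schwann cell myelin and fibroblast lists lie on the other side of 0, at 0.07 and -0.22.

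The average of the 3 differences was then tested. A single tissue can carry it, so a call on the average does not by itself show a change shared by the tissues. Nr1d1 was higher in each tissue, by log2 differences of 0.44 ± 0.14 in the cerebellum, 0.63 ± 0.14 in the spinal cord and 1.78 ± 0.14 in the nerve, and rose on average by 0.95 ± 0.08 (limma adjusted p = 0.0147). Both acrylamide arrays lay above both saline arrays in all 3 tissues. A probe set without a gene name, 1371689_at, named here after its values were seen, rose by 0.72 ± 0.07 (adjusted p = 0.021), with 0.58, 0.84 and 0.76 in the same order. Of 15773 probe sets these 2 passed, with 866 at an unadjusted p under 0.05 (626 with the random block), where chance gives 789. Next came Ddit4 (-0.55 ± 0.07), Gbp2 (0.56 ± 0.07) and Entpd5 (0.40 ± 0.05), each at an adjusted p of 0.0721 in limma, Asph (0.38 ± 0.05, 0.079) and the glutathione transferase gene Gstp1 (0.41 ± 0.06, 0.122). The call of Nr1d1 ended without cerebellum saline replicate 1 (adjusted p = 0.129), saline 2 (0.107), acrylamide 1 (0.0502) or acrylamide 2 (0.0699). It also ended without spinal cord saline 1 (0.0685), saline 2 (0.11) or acrylamide 2 (0.0742), and the range over 22 alternatives chosen beforehand was 0.00553 to 0.129. The count was 0 without cerebellum saline 1, saline 2 or acrylamide 2 or spinal cord saline 1, saline 2 or acrylamide 2, 1 without cerebellum acrylamide 1, and 35, 5, 4 and 5 without nerve saline 1, saline 2, acrylamide 1 and acrylamide 2.

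NRF2 and glutathione genes, which detoxify electrophiles, rose on average over the tissues, a test chosen after the data were seen: 21 of 23 were higher, with a mean log2 difference of 0.17 and a median of 0.12 (camera adjusted p = 5.84e-09). With an estimated correlation the list kept an adjusted p = 0.0402, and in fry, which asks only whether the genes move on balance one way, it had 0.00854. None passed limma over all genes, 7 had an unadjusted p under 0.05, and 5 passed adjusted over the list alone: Gstp1, Gsta1 (0.49 ± 0.10), Gstm1 (0.31 ± 0.07), Me1 (0.14 ± 0.04) and the quinone reductase gene Nqo1 (0.48 ± 0.14). Probe sets of glutathione transferases can bind transcripts of near-identical relatives. The tests of this list on the average take arrays of different tissues as independent, and the random block was not run for lists. Differences between replicates correlated between tissues of the same treatment, with r from 0.125 to 0.317. All 20 cholesterol synthesis genes were lower, with a mean of -0.20 (camera adjusted p = 8.04e-16, and adjusted p = 0.325 with an estimated correlation). In limma 13 of them had an unadjusted p under 0.05 and 0 passed either adjustment, and the mean was -0.13 without nerve saline replicate 2. Interferon-induced genes rose on average by 0.24, with 16 of 18 higher (camera adjusted p = 1.87e-07, and adjusted p = 0.325 with an estimated correlation). Gbp2 and Mx2 (0.61 ± 0.18) were among 4 past limma adjusted over the list alone. Of the list calls in single tissues, 0 of 9 in the cerebellum, 0 of 14 in the spinal cord and 0 of 15 in the nerve held with an estimated correlation, and of the 14 on average NRF2 held.

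**Figure D4:**
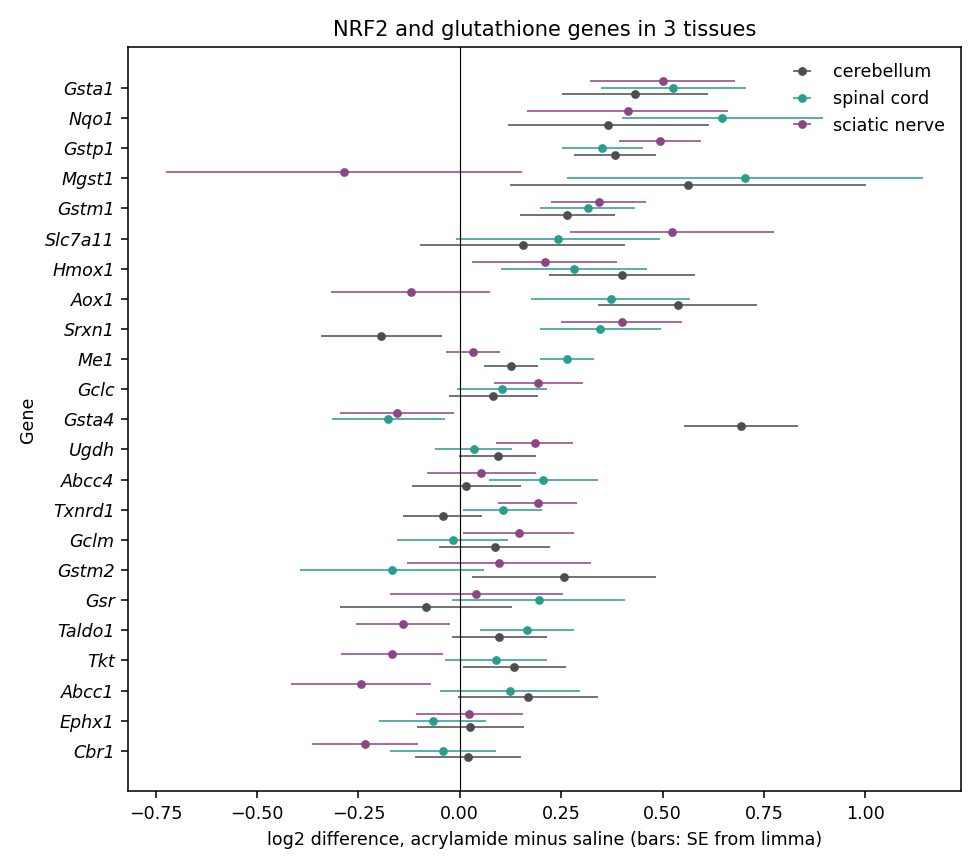
Log2 difference, acrylamide minus saline, with its standard error from limma (bars) for 23 NRF2 and glutathione genes in the cerebellum, spinal cord and sciatic nerve. Gstp1 lay at 0.38, 0.35 and 0.49, and Gsta4 at 0.69 in the cerebellum.

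Whether acrylamide differences depended on the tissue was asked with an F test over the tissue differences. Sptssb, which encodes a small subunit of serine palmitoyltransferase, had the smallest p (F = 27.04). Its nerve signals, 70.7 and 83.4 in saline and 17.5 and 11.9 in acrylamide arrays, all lay under the filter's 110, so their difference has no reliable size. Macroh2a1 had log2 differences of 0.41, -0.22 and -0.38 in cerebellum, cord and nerve (F = 25.97). Nr1d1 (F = 25.74) and Nr4a3 (F = 25.35), with differences of -2.42, -0.31 and 0.79, followed. Then came Syndig1l (F = 23.15), at -0.79 in the cord, and the neurexin ligand gene Nxph1 (F = 16.42), both with nerve signals under 110 on each array. None of them passed: limma's adjusted p was 0.609 for the first 4, 0.705 for Syndig1l and 1 for Nxph1. Over 21347 probe sets limma called 0, with 587 at an unadjusted p under 0.05, where chance gives 1067. It also called 0 in each pair of tissues, with 462 (cord and cerebellum), 817 (nerve and cerebellum) and 621 (nerve and cord). Without nerve saline replicate 2 the count was 1. At the level of lists, the acrylamide difference of immediate early genes was higher in the nerve than in the cerebellum by 0.98 (camera adjusted p = 1.1e-10, and adjusted p = 0.367 with an estimated correlation).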

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

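The tests of lists on differences between tissues were chosen after the results were seen. So were the tests of the clock genes and of cerebellar and spinal cord transcripts in the nerve. For the cord pattern, those of muscle and of an effect alike in roots and nerve were also chosen then. The tests of nerve root and bone genes in the cord were written before their results, though the bone markers were listed after the bone gene Bglap was seen to differ there.

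What singled out the lists of this paragraph and the next 2 was a difference between tissues in the size of the acrylamide effect, tested on the difference itself with camera and adjusted over lists and pairs of tissues. Of the 22 differences, 0 passed with an estimated correlation, and single arrays were not left out of these tests. Between the spinal cord and the cerebellum (cord minus cerebellum), circadian clock genes differed by 0.18 (adjusted p = 0.00531), reactive astrocyte genes by -0.24 (0.00282), collagen and extracellular matrix genes by -0.31 (8.61e-11) and skeletal muscle markers by -2.22 (0.000348). Each of these 4 had an adjusted p = 0.985 with an estimated correlation. The muscle difference rests on spinal cord saline replicate 1, without which the cord mean of the list was -0.05.

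Between the sciatic nerve and the cerebellum, immediate early genes differed by 0.98 (adjusted p = 1.1e-10, and adjusted p = 0.367 with an estimated correlation) and clock genes by 0.29 (0.000269 and 0.367). The other differences, with the same pair of adjusted p, were -0.23 for cholesterol synthesis genes (0.000233 and 0.973), -0.18 for fatty acid synthesis genes (0.0174 and 0.377) and 0.27 for cell cycle genes (0.00368 and 0.548). Interferon-induced genes differed by -0.28 (0.00662 and 0.955) and skeletal muscle markers by 1.48 (0.00353 and 0.973). The muscle difference rests on single nerve arrays, with a nerve mean of the list of 0.14 without saline replicate 2 and 0.05 without acrylamide replicate 2.

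Between the sciatic nerve and the spinal cord, skeletal muscle markers differed by 3.90 (adjusted p = 5.94e-13, and adjusted p = 0.563 with an estimated correlation), collagen and extracellular matrix genes by 0.32 (2.73e-11 and 0.563) and immediate early genes by 0.55 (1e-07 and 0.319). The muscle difference rests on these nerve arrays and on spinal cord saline replicate 1, without which the cord mean was -0.05. Cell cycle genes differed by 0.48 (1.78e-07 and 0.319), repair Schwann cell genes by 0.38 (0.000996 and 0.319) and reactive astrocyte genes by 0.295 (0.000985 and 0.563). Nerve fibroblast and perineurial markers differed by 0.28 (0.00282 and 0.754). Single arrays bear on these differences too. Without nerve saline replicate 2 the nerve mean of the fibroblast list changed sign and the nerve call of the astrocyte list ended. Without cord acrylamide replicate 2 the cord mean of the cell cycle genes changed sign. The acrylamide difference was lower in the nerve for cholesterol synthesis genes, at -0.165 (0.00368 and 0.781), and fatty acid synthesis genes, at -0.175 (0.0119 and 0.319). So it was for myelin genes of oligodendrocytes, at -0.25 (0.012 and 0.696), and autophagy and lysosome genes, at -0.086 (0.0425 and 0.563).

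In the spinal cord, collagen, Schwann cell and peripheral myelin lists were lower in the acrylamide arrays. Muscle in saline replicate 1 alone is argued against by means of -0.307 for collagen, -0.347 for Schwann cell myelin and -0.343 for Schwann cell markers without that array. Less nerve root tissue in the acrylamide pools is a candidate explanation: 76 other nerve-abundant genes had a median of -0.375 ± 0.047 (SE over genes, not between arrays) in the cord and -0.06 in the nerve, against 0.009 over all genes tested in the cord. Their cord median was -0.183 for acrylamide replicate 1 and -0.575 for replicate 2. Less bone cannot be told apart from these, since the 4 bone cell markers above the filter, of 6 on the arrays, had a median of -0.212 ± 0.232 (SE over genes), from Acp5 (-0.70) to Omd (0.13). The bone gene Bglap, seen before these markers were listed and not among them, had signals of 511 and 561 on the saline and 121 and 2.8 on the acrylamide cord arrays. An acrylamide effect alike in roots and nerve cannot be told apart either: the nerve means were 0.075 for collagen (-0.122 to 0.273 with 1 array left out), -0.16 for Schwann cell myelin (-0.396 to 0.072) and 0.008 for Schwann cell markers (-0.184 to 0.213), and an effect on the roots alone was not tested.

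Both replicate 1 arrays of the sciatic nerve held transcripts of cerebellar neurons, at a median of 10.98% (saline) and 13.8% (acrylamide) of the cerebellar level over 17 genes, against 1.62% and 1.33% on the replicate 2 arrays. These genes had been chosen as bright in the cerebellum and at least 16-fold lower in the cord, so cord tissue would not bring them at this level, and RNA of cerebellum in both arrays is a candidate explanation. Whether cord tissue was also present cannot be told apart from its absence, because 7 cord-restricted genes were at 5.85% and 3.6% of the cord level on the replicate 1 arrays and at 5.26% and 3.44% on the replicate 2 arrays. By another definition the values were 5.76% and 1.43%, and 0.61% and 0.48%, but it left 2 genes with a median of 7.68% on cord acrylamide replicate 2 itself, so these do not measure cord tissue. No biological explanation was tested, and the step at which such RNA entered stays open.

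Clock genes passed as a list in the sciatic nerve (9 of 15 higher, median 0.05, and adjusted p = 0.256 with an estimated correlation), led by Nr1d1 at 1.78 ± 0.14. Muscle in acrylamide replicate 2 is argued against by a difference of 1.757 ± 0.18 without that array, where the call ended (limma adjusted p = 0.146, in a range of 0.00468 to 0.9998 over alternatives chosen beforehand) with a larger standard error. Cerebellar RNA in the replicate 1 arrays is argued against by a difference of 1.949 without both of them. That value sets 1 saline against 1 acrylamide array, with median muscle signals of 92.2 and 1811, so it has no spread of its own. A different time of day at collection cannot be told apart from an acrylamide effect, since the times are not in the sources used here. Of the 6 clock genes past limma in the nerve when adjusted over the list, 5 had the same sign in the cord and 4 in the cerebellum, together 9 of 12, so both explanations stay open.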

How the results depend on the processing

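Tests without the 3 arrays with the most muscle or fat signal (spinal cord saline 1, sciatic nerve saline 1 and acrylamide 2), tests without both sciatic nerve replicate 1 arrays, and the tests of lists on the average were chosen after the data were seen. The other alternatives were planned.

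Differences between saline tissues stayed within 1.5 times their count under each alternative run, from 3167 to 5055 probe sets for the cord against the cerebellum and from 3957 to 6061 for the nerve against the cord. With 1 array left out they lay between 3944 and 4372 and between 4859 and 5631. The counts for acrylamide in the cerebellum (0), cord (0), nerve (1), the average (2) and the differences between tissues (0) lay, with 1 array left out, at 0 to 2, 0 to 1, 0 to 35, 0 to 35 and 0 to 1, with each 35 without nerve saline replicate 1. A group left with 1 array is assumed to vary like the others.

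In the cerebellum a fit of its arrays alone called 2. In the nerve, quantile normalization, a pseudocount of 64, no filter, the robust fit, 1 probe set per gene and a threshold of 0.1 each called 2. A fit of the nerve arrays alone called 0. A fit of 1 tissue alone has fewer residual degrees of freedom and a spread of its own. With it, probe sets at an unadjusted p under 0.05 went from 922 to 320 in the nerve. They went from 510 to 975 in the cerebellum and from 544 to 1023 in the cord, so fewer degrees of freedom alone do not explain the nerve. On the average, quantile normalization called 4, the fit without a trend called 1 and a threshold of 0.1 called 6. The 60th percentile filter and 1 probe set per gene, which test fewer probe sets, called 1 each. Under that filter Nr1d1 was not tested and the call was 1371689_at. With 1 probe set per gene, which leaves out probe sets without a gene name, it was Nr1d1. Apart from the settings that test fewer probe sets or use a higher threshold, the cause was not tested.

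With the replicate block within each tissue, the nerve count was 0, with Nr1d1 at an adjusted p of 0.127 (0.000285 to 0.9998 over its alternatives), and the average count was 6, as with a block over all tissues (6). Under the block within tissues the calls of heat shock (camera adjusted p = 0.0516) and cell cycle genes (0.0503) in the cord and of ER chaperones (0.0545) and ribosomal protein genes (0.0613) in the nerve ended. Replicates share a number in the labels and nothing else that is stated, and the cause was not tested.

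Without the 3 arrays rich in muscle or fat, counts were 2 in the cerebellum, 998 in the nerve, 834 on the average and 1024 for differences between tissues, and 24 lists passed in the nerve and 24 on the average. Without both nerve replicate 1 arrays they were 2, 381, 197 and 98, and 24 lists passed in the nerve. Each nerve group then holds 1 array, with its spread borrowed from the other groups. The 998 sets saline replicate 2, with few cerebellar transcripts, against acrylamide replicate 1, which held them, and the 381 sets saline replicate 2 against acrylamide replicate 2, with median muscle signals of 92.2 and 1811, so neither size can be read as an effect of acrylamide.

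Lists past camera in the cerebellum (9), cord (14), nerve (15) and on the average (14) fell to 0, 0, 0 and 1 with an estimated correlation and to 0, 0, 0 and 1 in fry, where NRF2 and glutathione genes were the 1 that passed. With 1 array left out and the preset correlation there were 4 to 13, 9 to 19, 14 to 27 and 11 to 24. The cause was not tested. Of 52 list calls, quantile normalization left 47 with the same direction and side of the threshold, and a pseudocount of 64 left 49. Of 320 list tests with 1 array left out, 258 kept the direction of the test and the side of the threshold, 57 missed the threshold and in 5 the test turned.

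Genes whose difference, and lists whose test, turned when 1 array was left out are given as the lowest and highest value over the arrays left out, and the cause was not tested. In the nerve, Mag went from -0.518 to 0.003, Sfrp4 from -0.139 to 1.698, Pvalb from -0.35 to 3.032, Schwann cell myelin genes from -0.396 to 0.072 and fibroblast markers from -0.218 to 0.611, each turning without saline replicate 2. Lpl went from -1.047 to 0.105, Cidea from -1.073 to 0.105 and fat cell markers from -1.358 to 0.465, each turning without saline replicate 1, and without both replicate 1 arrays they were at 0.256, 0.369 and 0.663. Without the 3 arrays fat cell markers were at 0.269 and ER chaperones at 0.019 with a test leaning down. Ribosomal protein genes were at 0.014 under quantile normalization, and from -0.079 to -0.01 with 1 array left out, and their test leaned up without acrylamide replicate 1 and without both replicate 1 arrays (0). In the cord, muscle markers went from -4.718 to -0.053, the latter without saline replicate 1, where the test leaned up. The mean alone changed sign, with the test leaning as before, without acrylamide replicate 2 for oligodendrocyte myelin genes (0.097) and ER chaperones (-0.001) in the nerve and cell cycle genes in the cord (0.006). It also did so for oligodendrocyte myelin genes without the 3 arrays (0.04) and for fatty acid synthesis genes without both replicate 1 arrays (0.004).

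Of 207 differences of named genes, all kept direction and side under median centring, no filter, no trend, the block over all tissues and the random block, and 206 did so with a pseudocount of 64 and in the robust fit, where 1 passed the threshold newly. Of 1000 values of named genes with 1 array left out, 969 kept both, 17 passed the threshold newly, 9 missed it and 5 turned. Apart from Nr1d1, the named acrylamide differences were not past the threshold, so they kept their side by staying uncalled. The 9 that missed it were all values of Nr1d1, in the nerve or on the average. Under the 60th percentile filter, named genes below it gave no value and 169 kept both. A dim gene's difference is understated by the pseudocount of 16, and no background per probe set was used, so changes of genes near or under a signal of 110 are beyond these tests.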

Other observations

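The test of the same rats, the count of splits by called genes, the 3 splits by replicate number and the tests of lists on the average of the tissues were chosen after the results were seen; the counts of splits for lists were written before.

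Granulocyte and mast cell markers were lower in the cord with acrylamide, with a mean log2 difference of -1.845 over 6 genes (camera adjusted p = 0.00583, and adjusted p = 0.816 with an estimated correlation). Of them 1 was higher, 5 were lower, 1 had an unadjusted p under 0.05 in limma, and 0 passed either adjustment. The alarmin gene S100a9 had signals of 3261 and 5950 on the saline and 3951 and 366.8 on the acrylamide arrays, and the cathelicidin gene Camp 341.5 and 623, and 295 and 4.1. The call ended without saline replicate 2 (mean -1.42, 0.213) or acrylamide replicate 2 (-0.295, 0.708), and the mean was -3.38 without acrylamide replicate 1. Bglap, a bone gene, had signals of 511 and 561, and 121 and 2.8.

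On the average over the tissues, where limma called 0 members of the lists of this paragraph, 2 further lists fell. Heat shock proteins had a mean log2 difference of -0.08 over 13 genes (camera adjusted p = 0.00359, and adjusted p = 0.29 with an estimated correlation), and 4 had an unadjusted p under 0.05. Past limma adjusted over the list were Hspa1a (-0.42 ± 0.08), Dnajb1 (-0.24 ± 0.06) and Cryab (-0.23 ± 0.06). Glucocorticoid-induced genes had a mean of -0.125 over 15 genes (camera adjusted p = 0.00463, and adjusted p = 0.433 with an estimated correlation), with 3 at an unadjusted p under 0.05 and Angptl4 (-0.51 ± 0.13) past the list alone. Without nerve saline replicate 1 the camera adjusted p was 0.106 for heat shock proteins (mean -0.06) and 0.084 for glucocorticoid-induced genes, which also ended without nerve acrylamide replicate 1 (0.0597).

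Myelin genes of Schwann cells (14 tested, mean -0.12, camera adjusted p = 7.58e-05, and adjusted p = 0.473 with an estimated correlation), Schwann cell markers (5, -0.135, 0.017, and adjusted p = 0.439 with an estimated correlation) and fatty acid synthesis genes (17, -0.08, 0.0324, and adjusted p = 0.325 with an estimated correlation) also fell on the average. In limma 4, 2 and 5 of their members had an unadjusted p under 0.05, 0 passed over all genes, and 0, 0 and 2 passed adjusted over the list alone. The myelin call ended without nerve saline replicate 2 (-0.05, 0.0748). That of the Schwann cell markers ended without cerebellum saline replicate 2 (0.0504) or nerve saline replicate 2 (-0.07, 0.263). That of the fatty acid genes ended without cerebellum saline 2 (0.0852), cord saline 1 (0.0791), cord acrylamide 1 (0.094) or nerve acrylamide 1 (0.275). Both of these calls also ended under quantile normalization (0.0898 for each).

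Clock genes rose on the average, with a mean of 0.10 and a median of 0.02 over 15 genes (camera adjusted p = 0.00463, and adjusted p = 0.325 with an estimated correlation). Beside Nr1d1, members past limma adjusted over the list were Dbp (0.35 ± 0.06), Nr1d2 (0.32 ± 0.08), Per3 (0.24 ± 0.07) and Bhlhe41 (0.24 ± 0.07) among 6. Microglia and macrophage markers (16 tested) had a mean of 0.29 (camera adjusted p = 8.13e-06, and adjusted p = 0.52 with an estimated correlation), with Fcgr2b (0.59), Lgals3 (0.56) and Gpnmb (0.465) past the list alone. MHC class II genes (7) had 0.38 (0.0026, and adjusted p = 0.52 with an estimated correlation) and complement genes (9) 0.18 (0.017, and adjusted p = 0.723 with an estimated correlation). Reactive astrocyte genes (13) had 0.15 (0.00123, and adjusted p = 0.325 with an estimated correlation) and autophagy and lysosome genes (26) 0.05 (0.00463, and adjusted p = 0.325 with an estimated correlation). In the order of these 5 lists, 5, 2, 0, 4 and 2 members had an unadjusted p under 0.05 in limma, 0 passed over all genes, and 3, 0, 0, 1 and 1 passed adjusted over the list alone.

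Without nerve saline replicate 2 the calls of microglia markers (mean 0.08, camera adjusted p = 0.17), MHC class II genes (0.14, 0.0748) and complement genes (0.003, 0.968) ended. Without nerve saline replicate 1 these means were 0.50, 0.61 and 0.36. The complement call also ended without cord acrylamide 1 (0.0541) or nerve acrylamide 2 (0.165), and the autophagy call without nerve saline 1 (0.0587) or nerve acrylamide 2 (0.0778).

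The treatment labels were exchanged within tissues in 100 of 108 possible splits, the real one among them. For the count of probe sets past limma on the average, chance cannot be excluded: 35 of the 100 splits gave as many as the real 2, and the highest other gave 553. Apart from the real one these were the 33 splits that parted the nerve arrays by replicate number, 0 of 31 that parted them by treatment and 1 of 35 others. The 33 splits that parted the nerve arrays by replicate number called 322 to 553 with a median of 372, which points to a structure of the samples, the differences between the replicate 1 and 2 arrays of the nerve. For the count of lists chance cannot be excluded either, with 44 of the 100 at or above the real 14 and the highest other at 20. For NRF2 and glutathione genes 1 split, the real one, reached its p of 0.000803 with an estimated correlation, against 0.00435 in the next. For cholesterol synthesis genes 1 split, the real one, reached its p of 0.052, against 0.0777 in the next, and that p did not pass. Whether chance can be excluded stays open for both lists. At least 1 list of any kind passed with an estimated correlation in 22 of the 100 splits. Apart from the real one, each of these parted the nerve arrays by replicate number. All splits take arrays of different tissues as independent. If equal replicate numbers mark shared pools, 3 splits keep the pools together, too few for a share under 0.05, and the lowest p of the other 2 was 0.569 for NRF2 and 0.363 for cholesterol genes.

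Differences between replicates 1 and 2 correlated between tissues of the same treatment, with a mean r of 0.193 over 6 pairs (0.125 to 0.317) and 15773 probe sets, against 0.05 between tissues of different treatment. The real numbering gave the highest mean of the 16 ways to exchange numbers, and the next was 0.095. Its exact p of 0.0625 is the smallest that 16 exchanges can give, so whether equal numbers mark the same rats in the 3 tissues stays open. Within a tissue, the same differences correlated between the treatments with r of 0.092 in the cerebellum, -0.086 in the cord and 0.329 in the nerve.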
